A study of Rattus norvegicus with 6 samples.

How the data were processed

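The series profiled RNA from the spinal cord of Sprague-Dawley rats weighing 200 to 250 g, per the labels. It holds 6 libraries in 2 groups: 3 from sham-treated rats (Sham) and 3 after ischemia-reperfusion injury of the cord (SCII), in which blood flow is interrupted and then restored. Total RNA was made into stranded paired-end libraries after removal of ribosomal RNA, per the labels' protocols. The labels do not say that the replicates of a group came from separate animals, so the p-values below measure the spread between these samples. The duration of ischemia and the time of sampling are not given in the sources used here.

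The authors deposited one table of mRNA transcripts and one of lncRNA transcripts (long non-coding RNA), each with 1 column per library, and the values in both were read as FPKM (fragments scaled to transcript length and to sequencing depth). The file headers do not name the unit. It was inferred from non-integer values whose totals differ between libraries. Trimmomatic, HISAT2, Cufflinks, HTSeq, StringTie and DESeq and the build Rnor_6.0 are named per the submitters' processing notes, without roles or versions. The low values showed no steps from which whole reads could be recovered, so depth is unknown, no count model was used and no counting interval is given. The mRNA total ranged from 345128 FPKM in SCII 2 to 452687 FPKM in SCII 3, and the lncRNA total from 226018 FPKM in Sham 1 to 590155 FPKM in Sham 3. These totals are not depths.

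The mRNA table held 55760 RefSeq transcripts (17498 curated and 38262 predicted accessions). Of these, 32081 (57.5%) were matched to a gene symbol by accession without version in the RefSeq gene table of the assembly GRCr8, 12168 of them with the version as well. The FPKM of transcripts of a symbol were summed, which gave 17725 genes. The unmatched transcripts carried 12.5% to 14.7% of the mRNA FPKM of a library and were tested separately. Transcripts of a gene with identical sequence parts can share or double reads in such a sum. Globins and other families of near-identical copies are uncertain for the same reason. The lncRNA table held 25328 transcripts (24879 NONCODE and 449 assembled identifiers), and 0 were matched to a symbol, so lncRNAs were analysed by identifier. The planned comparison of lncRNAs with neighbouring genes and the planned list of named lncRNAs were not analysed here.

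The comparison was SCII against Sham. Before the data were examined, a test for normalised values was fixed: limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and a mean-variance trend, two-sided, on features with at least 1 FPKM in at least 3 libraries. The Benjamini-Hochberg adjusted p threshold was 0.05 within each table, without a block for replicate number. Summing to genes was chosen after the mRNA table was seen to hold transcripts. The filter left 10717 genes and 5340 lncRNA transcripts. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. With 3 samples against 3, an exact permutation test of a single gene cannot go below p = 0.1, so none was run.

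Also fixed before the data were examined were 15 primary and 20 secondary gene lists, from textbook markers of cord cells, injury responses and other cell types a dissection can hold. For each list, members past the threshold were counted with adjustment over all genes and over the list alone. Lists of 3 or more measured members were tested by camera in limma with a preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. Older symbols were updated through synonyms. Named genes followed a rule fixed at the same time: the 5 largest rises and the 5 largest falls among genes past the threshold whose groups did not overlap and whose mean was at least 1 FPKM; for each primary list the 2 members past the threshold with the lowest adjusted p, or the 1 with the lowest p where none passed; for each secondary list the 1 member past the threshold with the lowest adjusted p; and the largest changes among lncRNAs, of which at most 2 identifiers per direction are printed. Other list members named below were chosen as examples after their values were seen. The share of called lncRNAs was compared with that of mRNA genes matched on mean expression in bins of 0.5 on the log2 scale, over 100 seeded draws.

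The scripts were tested on simulated data built from the means and residual spreads of the real libraries, with 200 changed features per table. Each feature was drawn independently, with the same spread in both groups. The simulation held no outlying library, no correlation between genes and no shift of all genes. The rates below may therefore not hold for the real libraries. For the 10717 mRNA genes the test recovered 66% of genes lowered by 2 on the log2 scale, 78% of those raised by 2, 32% of those lowered by 1 and 38% of those raised by 1, and it called 0.038% of unchanged genes. For the 5340 lncRNAs it recovered 28% and 48% of transcripts lowered and raised by 2, and 6% and 2% of those lowered and raised by 1. Alternatives were a replicate block, no trend, quantile normalization, median centring, other filters, a pseudocount of 0.1, a fold threshold and leaving out each library. Transcript-level features, library weights and the counts of each list without single libraries were added after the data were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.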

Results

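RNA of the rat spinal cord was compared between 3 sham-treated samples (Sham) and 3 samples after ischemia-reperfusion injury (SCII), as FPKM of mRNA and of lncRNA. The comparison asks which coding and non-coding transcripts differ in the injured cord. Between 17116 (SCII 2) and 20718 (Sham 2) mRNA transcripts per library reached 1 FPKM, and between 4462 (SCII 2) and 5648 (SCII 1) lncRNA transcripts did. The reads behind these values are unknown. The first principal component of the mRNA genes held 82.2% of the variance. It placed the Sham libraries at −50.1 to −44.7, SCII 3 at 13.3, SCII 1 at 27.0 and SCII 2 at 103, so that SCII 2 stood apart from the other SCII libraries. The median log2(FPKM + 1) of the tested genes was 2.80 in SCII 2 and between 3.22 and 3.34 in the others.

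**Figure D1:**
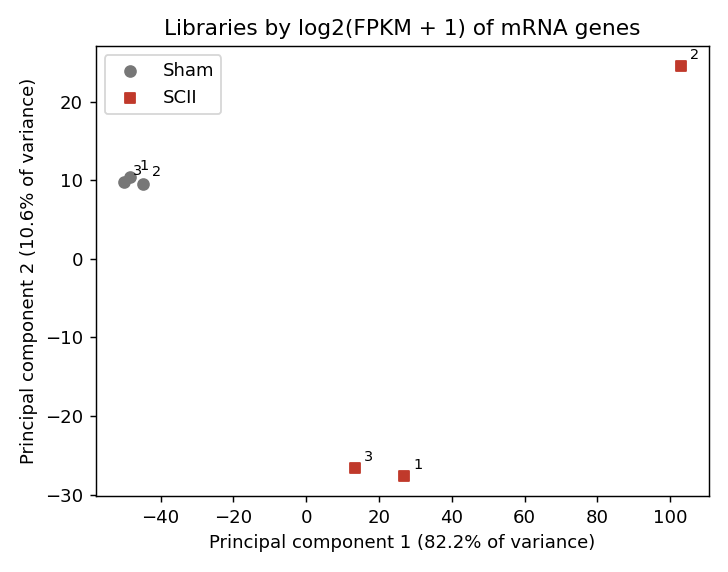
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over 10717 mRNA genes, with the share of variance on each axis and the replicate number beside each point. The Sham libraries lie together at −50.1 to −44.7 on the first component and SCII 2 lies farthest from them, at 103.

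The largest rises were those of cytokine, chemokine and protease inhibitor transcripts. Il6, an inflammatory cytokine, went from 0.106 ± 0.0632 FPKM in Sham to 122 ± 1.16 FPKM in SCII (SD, n = 3 per group), a log2 change of 6.80 ± 0.12 (SE). The monocyte chemokine Ccl2 rose from 1.70 ± 0.927 to 421 ± 109 FPKM, and the neutrophil chemokine Cxcl1 from 0.631 ± 0.343 to 234 ± 60.4 FPKM. Serpine1, which inhibits plasminogen activators, rose from 0.513 ± 0.0155 to 246 ± 62.7 FPKM, and the protease inhibitor Slpi from 0.564 ± 0.557 to 326 ± 160 FPKM. These had the largest positive log2 changes under the naming rule, from 6.80 for Il6 to 7.65 for Slpi, each with a limma Benjamini-Hochberg adjusted p of at most 0.00035. The largest falls were smaller. Slco1c1 and Slco1a4, transporters of the blood-brain barrier, went from 25.9 ± 2.02 to 4.05 ± 3.19 FPKM and from 20.9 ± 4.87 to 2.62 ± 1.59 FPKM. Slc2a5, a fructose transporter of microglia, went from 5.04 ± 0.641 to 0.596 ± 0.551 FPKM, Nnmt from 3.55 ± 1.14 to 0.201 ± 0.348 FPKM, and Prom1, which encodes a membrane glycoprotein, from 8.33 ± 1.97 to 1.43 ± 0.120 FPKM. Their log2 changes lay between −2.69 for Slco1c1 and −1.93 for Prom1, with adjusted p from 0.0026 for Prom1 to 0.029 for Slco1c1. Slco1c1 lost its call without Sham 1 (adjusted p = 0.115), Sham 2 (0.104), Sham 3 (0.108) or SCII 1 (0.0658), without a filter (0.0540) and with a pseudocount of 0.1 (0.0587), and Slc2a5 without Sham 1 (0.0527) or Sham 3 (0.0509).

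Of 10717 mRNA genes tested with limma, 1180 were higher and 426 lower in SCII at a Benjamini-Hochberg adjusted p under 0.05, and 784 and 196 of these changed by at least 1 on the log2 scale. In 64.6% of genes the groups did not overlap, where chance gives 10%; SCII lay above Sham in 2253 of these genes and below in 4674, so they ran the other way from the called genes. The median log2 change of all tested genes was −0.29. After median centring of the libraries 1466 genes were higher and 1444 lower, and after quantile normalization 1634 and 1562. The median log2 change was then −0.11 in each, less negative than before. A shift of all genes therefore does not by itself give the added lower calls. Without rescaling, library weights, which gave SCII 2 the lowest weight, gave 2212 higher and 4201 lower. The balance of directions thus moved with scaling and with the weight of SCII 2. List medians below are given relative to the median of all genes, which raises each. Without this reference the heat shock median was 0.07 and the endothelial median 0.12. The counts moved with single libraries. Without SCII 2 they were 1888 higher and 3312 lower, without SCII 3 they were 1295 and 2034, and without SCII 1 they were 694 and 96. They were 409 and 21 without Sham 1, 605 and 36 without Sham 2, and 382 and 20 without Sham 3. Each fit without a library also has fewer residual degrees of freedom, and the fits without a Sham library keep SCII 2. A call lost in such a fit, here and below, need not mean that it rests on the library left out.

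**Figure D2:**
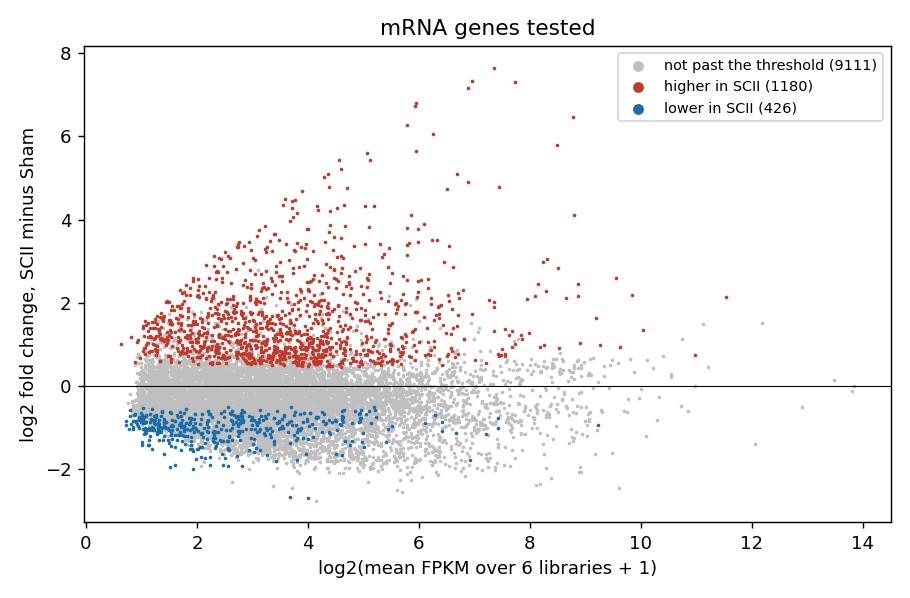
The log2 fold change of SCII minus Sham (vertical axis) against log2 of the mean FPKM plus 1 (horizontal axis) for 10717 mRNA genes, 1 point per gene. Red points are the 1180 genes higher and blue points the 426 genes lower at a limma adjusted p under 0.05; rises reach further from 0 than falls.

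Cytokines and chemokines rose most among the lists. Of 21 measured members 19 were higher (20 adjusted over the list alone) and 0 lower, with a list median of 4.75 relative to all genes. Besides Il6, the neutrophil chemokine Cxcl2 rose from 0.123 ± 0.0222 to 120 ± 23.6 FPKM, Il1b from 0.462 to 39.3 FPKM and the cytokine Lif from 0.0428 to 44.9 FPKM. Ccl5 and Tnfsf9 did not pass. Of 10 neutrophil markers 9 were higher (9 adjusted over the list alone), with a median of 3.36. Without a filter 10 of 19 were higher and the median was 2.09. A gene under 1 FPKM in all Sham libraries passes the filter only if all 3 SCII libraries reach 1 FPKM, which favours rises. Lcn2, which binds bacterial siderophores and is also on the reactive astrocyte list, rose from 2.54 ± 0.921 to 68.2 ± 4.99 FPKM. The chemokine receptor Cxcr2 rose from 0.0472 ± 0.0313 to 9.25 ± 3.95 FPKM. Of 12 leukocyte adhesion genes 8 were higher and 1 lower (the same counts adjusted over the list alone), with a median of 1.98. Cd44 rose from 9.29 ± 1.12 to 115 ± 28.2 FPKM and Icam1, an endothelial ligand of leukocyte integrins, from 1.81 ± 0.691 to 21.5 ± 3.19 FPKM, and Vcam1 was the member called lower. The adhesion genes called higher were 4 without Sham 1, 5 without Sham 2 and 3 without Sham 3. Vcam1 lost its call in these fits, without SCII 1 and with a replicate block, while 2 members were lower without SCII 2. With a filter of 5 FPKM, 7 members were measured, of which 5 were higher and 1 lower. All 3 lists passed camera with the preset correlation and none did with an estimated one: the adjusted p was then 0.087 for cytokines, 0.236 for neutrophil markers and 0.236 for adhesion genes. Camera at the preset correlation called 9 of the 15 primary lists, and other splits of the 6 libraries, which mix Sham and SCII, gave up to 11.

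Markers of myeloid cells divided by list. Of 21 markers of macrophages and activated myeloid cells, 14 were higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 1.95 relative to all genes. The Fc receptor Fcgr2b rose from 2.46 ± 0.370 to 24.0 ± 2.35 FPKM and the lipopolysaccharide co-receptor Cd14 from 1.52 ± 0.422 to 23.4 ± 4.20 FPKM, and Trem2, a lipid receptor of microglia, fell from 6.40 to 1.62 FPKM. The activated myeloid markers called higher were 6 without Sham 1 or Sham 3 and 7 without SCII 1, and 2 were lower without SCII 2. Of 12 homeostatic microglia markers 4 were lower and 0 higher (7 lower adjusted over the list alone), with a median of −0.66. The growth factor receptor Csf1r fell from 20.4 ± 0.998 to 9.998 ± 1.39 FPKM but lost its call without Sham 1 (adjusted p = 0.0711) or Sham 3 (0.0683). The microglia markers called lower were 1 without Sham 1, 2 without Sham 2, 0 without Sham 3 (8 at an unadjusted p under 0.05 by limma with all 6 libraries) and 8 without SCII 2. Both lists passed camera with the preset correlation, but not with an estimated one (adjusted p = 0.184 for activated myeloid and adjusted p = 0.236 for microglia), and without SCII 3 the microglia list did not pass with the preset correlation either (adjusted p = 0.0715).

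Astrocyte genes also divided by list. Of 22 reactive astrocyte genes 20 were higher (20 adjusted over the list alone), with a median of 3.09 relative to all genes. Socs3, a feedback inhibitor of cytokine signalling, rose from 1.23 ± 0.204 to 149 ± 30.8 FPKM, Ptx3 from 0.256 ± 0.0758 to 46.4 ± 11.1 FPKM and Timp1, an inhibitor of metalloproteinases, from 11.5 to 701 FPKM. Gfap, the intermediate filament of astrocytes, was 469 FPKM in Sham and 397 FPKM in SCII and did not pass (adjusted p = 0.51 by limma), and neither did Hspb1. The list passed camera with the preset correlation and had an adjusted p = 0.087 with an estimated correlation. Of 18 homeostatic astrocyte markers 0 passed limma over all genes and 0 over the list alone (1 at an unadjusted p under 0.05). Their median was −1.07 relative to all genes, and the camera adjusted p was 0.067. The lowest p belonged to Fgfr3, at 7.11 ± 1.93 and 3.01 ± 2.33 FPKM (adjusted p = 0.103). The medians of this list against the Sham mean were −0.41 in SCII 1, −3.07 in SCII 2 and −0.69 in SCII 3, and without SCII 2, 10 members were lower and 1 was higher. The median relative to all genes was −0.40 without SCII 2. With the preset correlation the list call was close to the threshold. It passed camera without SCII 1 (adjusted p = 0.0067), without SCII 2 (0.0147), with median centring (0.0353) and with quantile normalization (0.0293). It also passed without a filter (0.0431) and with a filter of 5 FPKM (0.0465), but not with a pseudocount of 0.1 (0.0685) or library weights (0.220). With an estimated correlation, which was 0.92, the camera adjusted p was 0.691.

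The same library set the spread of neuron and myelin genes. Of 29 neuron and synapse genes 1 passed, Snca (alpha-synuclein), which was higher, at 53.9 ± 9.79 FPKM in Sham and 91.3 ± 14.1 FPKM in SCII (adjusted p = 0.049). Snca lost its call in every fit without a single library except that without SCII 2, with adjusted p up to 0.178, as well as without a trend, without a filter, with a filter of 5 FPKM and with a pseudocount of 0.1 (0.0512 to 0.0636), and 0 members passed over the list alone (14 were lower at an unadjusted p under 0.05). The list median was −1.44 relative to all genes and passed camera with the preset correlation (adjusted p = 0.0027), but not with an estimated correlation (adjusted p = 0.668). Against the Sham mean the list median was −0.97 in SCII 1, −3.44 in SCII 2 and −0.65 in SCII 3. Snca had 76.0, 104 and 93.9 FPKM in SCII 1, 2 and 3, so it was highest where the list was lowest. It does not stand for the list, and which cells its RNA came from was not tested. The neurofilament gene Nefl had 1212 FPKM in Sham and 336 FPKM in SCII, and the synaptic gene Snap25 694 and 254 FPKM. Without SCII 2, 25 members were lower and 1 was higher, and without SCII 3, 8 were lower; the median relative to all genes was −0.64 without SCII 2. With median centring or quantile normalization 3 were lower.

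Of 23 myelin and oligodendrocyte markers 1 passed (1 over the list alone). This was Sox10, a transcription factor of oligodendrocytes and Schwann cells, which rose from 21.4 ± 0.655 to 39.99 ± 1.76 FPKM and lost its call without Sham 1 (adjusted p = 0.0547) or Sham 3 (0.0556). The list median was −0.98 relative to all genes (camera adjusted p = 0.063). Myelin genes such as Plp1, with 5575 FPKM in Sham and 2896 FPKM in SCII, did not pass. Medians against the Sham mean were −0.30, −2.93 and −0.56 in SCII 1, 2 and 3, and without SCII 2, 9 members were lower. The myelin median relative to all genes was then −0.26. With the preset correlation the myelin list passed camera without Sham 2 (adjusted p = 0.0211) or SCII 1 (0.0077), with median centring (0.0331) and with quantile normalization (0.0187). It also passed without a filter (0.0452), but not with a pseudocount of 0.1 (0.0584) or library weights (0.176). With an estimated correlation, which was 0.76, the camera adjusted p was 0.691. Of 12 motor neuron and cholinergic genes 1 was higher (8 lower and 1 higher adjusted over the list alone), with a median of −0.99 and a camera adjusted p of 0.151. The one that rose, Mmp9, encodes a metalloproteinase that is also a neutrophil marker, and went from 0.119 ± 0.0917 to 8.75 ± 3.98 FPKM. The choline transporter gene Slc5a7 had 20.5 FPKM in Sham and 5.49 FPKM in SCII and did not pass. Medians were −0.62, −2.58 and −0.78 in SCII 1, 2 and 3, and without SCII 2, 10 members were lower and the list passed camera (adjusted p = 0.0478, median −0.60 relative to all genes), as it did without a filter (0.0478). Without SCII 3, 1 member was lower, with median centring 5 and with quantile normalization 7. With an estimated correlation the camera adjusted p of the motor neuron list was 0.671.

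**Figure D3:**
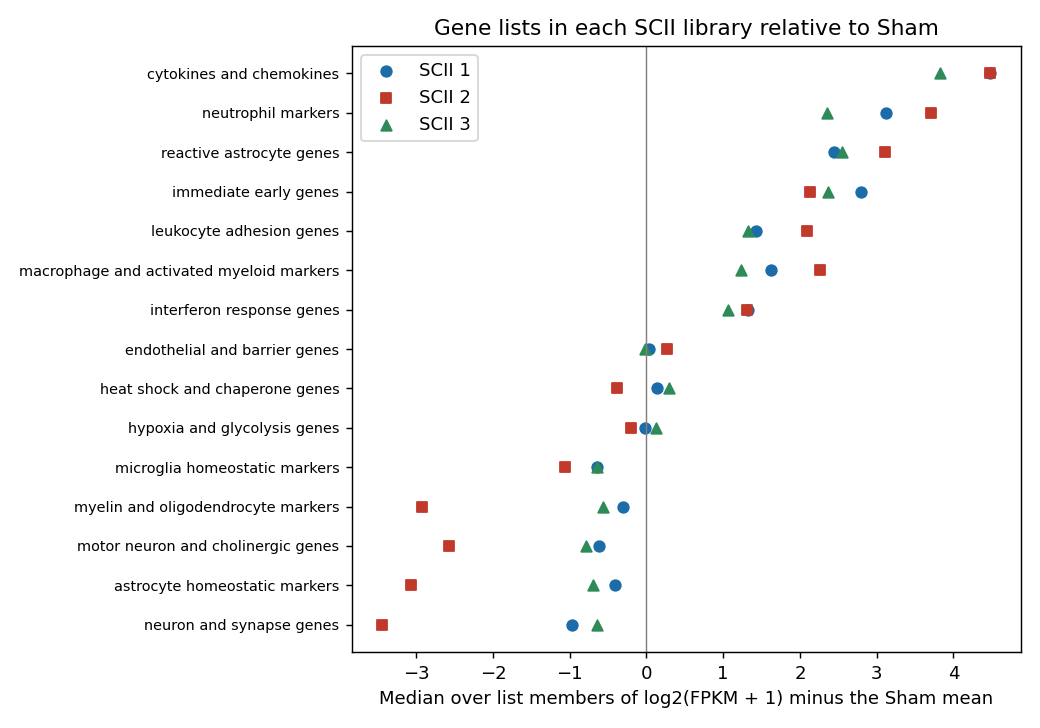
Median over the measured members of each primary gene list of log2(FPKM + 1) in 1 SCII library minus the Sham mean (horizontal axis), with 1 marker per SCII library. Inflammatory lists lie above 0 in all 3 SCII libraries, and neuron genes lie at −0.97, −3.44 and −0.65 in SCII 1, 2 and 3.

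Of 25 immediate early genes, which encode transcription factors and regulators induced within minutes of stimulation, 23 were higher (24 adjusted over the list alone), with a median of 2.99 relative to all genes. Fosl1 rose from 0.150 ± 0.0339 to 37.1 ± 8.13 FPKM, the phosphatase gene Dusp5 from 0.694 ± 0.122 to 13.4 ± 1.88 FPKM. The list passed camera with the preset correlation and had an adjusted p = 0.087 with an estimated correlation. Of 20 heat shock and chaperone genes 3 were higher (3 over the list alone), with a median of 0.37 and a camera adjusted p of 0.063. Without SCII 2, 8 were higher and 2 lower, and the camera adjusted p was 0.0024. With median centring 5 were higher and it was 0.0254, and with quantile normalization 5 and 0.0514. With library weights 8 were higher and 3 lower, and it was 0.0152. Without a filter the median was 0.17. With an estimated correlation the camera adjusted p was 0.668. The 3 genes of the first count were Hspa1a, which rose from 1.40 ± 0.472 to 14.4 ± 1.06 FPKM, its co-chaperone Bag3, from 8.61 ± 0.698 to 33.6 ± 2.25 FPKM, and Cryab, from 168 to 766 FPKM. The abundant Hspa8 had 1035 and 1021 FPKM. Of 25 hypoxia and glycolysis genes 7 were higher and 1 lower (7 and 2 over the list alone; median 0.27, camera adjusted p = 0.132). The median without reference to all genes was −0.02 and turned positive with median centring. Lactate dehydrogenase A (Ldha) rose from 64.0 ± 7.97 to 537 ± 216 FPKM and hexokinase 2 (Hk2) from 1.10 ± 0.299 to 13.4 ± 6.70 FPKM, and Ddit4 was the member called lower. These counts moved with single libraries: 2 members were higher without Sham 1 or Sham 3, 3 without Sham 2 and 4 without SCII 1, Ddit4 lost its call without each Sham library, and 8 were higher and 6 lower without SCII 2, and 7 and 2 without SCII 3. With quantile normalization 2 were lower, and with a filter of 5 FPKM the median relative to all genes was −0.07.

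Of 27 interferon response genes 16 were higher (21 adjusted over the list alone), with a median of 1.51 relative to all genes. Cxcl11 rose from 0.138 ± 0.112 to 11.2 ± 0.619 FPKM and the GTPase gene Gbp2 from 2.66 ± 0.642 to 43.6 ± 17.4 FPKM. Without Sham 1, 8 members were higher, and without Sham 3, 7. The list passed camera with the preset correlation and had an adjusted p = 0.229 with an estimated correlation. Of 21 endothelial and barrier genes 4 were higher and 6 lower (6 and 6 over the list alone), with a median of 0.41 and a camera adjusted p of 0.377. The members that fell included Slco1a4 and the efflux transporter Abcb1a (10.7 ± 1.88 to 3.49 ± 0.849 FPKM), which lost its call without Sham 1 (adjusted p = 0.0551). Called higher and lower were 0 and 2 without Sham 1 (6 higher at an unadjusted p under 0.05 by limma with all 6 libraries), 2 and 3 without Sham 2, 1 and 2 without Sham 3, and 3 and 3 without SCII 1. The median relative to all genes was 0.22 without SCII 2, 0.25 without a filter and 0.17 with a filter of 5 FPKM.

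**Figure D4:**
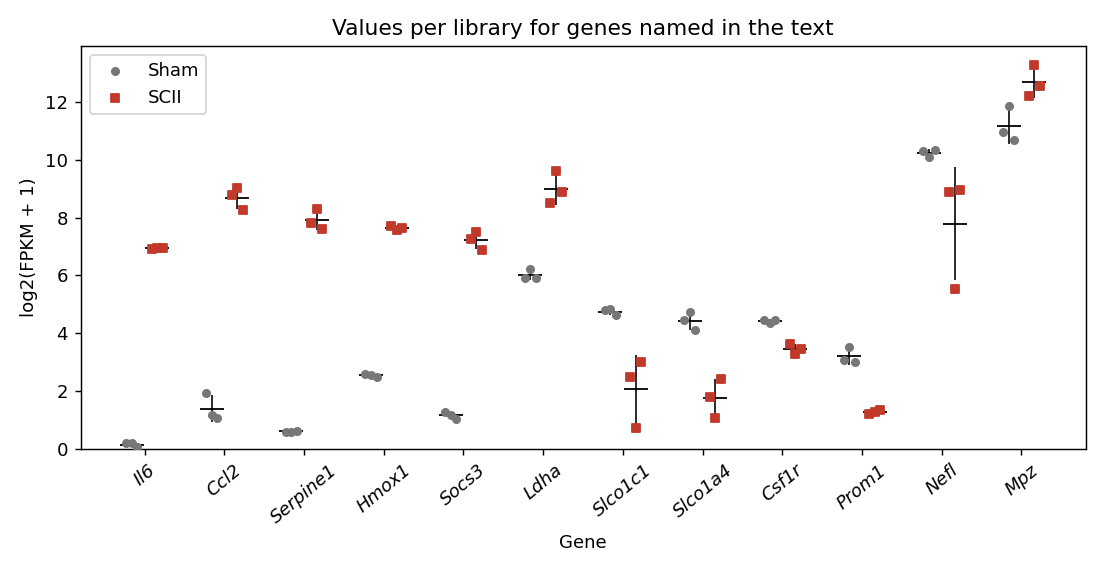
log2(FPKM + 1) per library (vertical axis) for 12 genes named in the text (horizontal axis), with circles for Sham, squares for SCII, a horizontal dash for the mean and a vertical bar for the SD (n = 3). Il6 rises from 0.106 to 122 FPKM with little spread, and Nefl shows the wide spread of SCII that neuron genes had.

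Secondary lists that hold injury responses gave the following. Of 21 extracellular matrix and scar genes 13 were higher (14 over the list alone), with a median of 2.27 relative to all genes. Serpine1 and Thbs1 (6.52 to 228 FPKM) were among them, while Col1a1 and Col3a1 did not pass; 8 were higher without Sham 1 or Sham 3. Of 22 cell death genes 12 were higher (15 over the list alone; median 1.01), with Ripk3, a kinase of necroptosis, from 0.447 ± 0.208 to 7.66 ± 1.51 FPKM; 5 were higher without Sham 1, without Sham 2 or without Sham 3. Of 21 antioxidant and iron genes 9 were higher (10 higher and 2 lower over the list alone; median 0.66), with the haem-degrading enzyme Hmox1 from 4.87 ± 0.208 to 198 ± 10.3 FPKM and the metallothionein Mt1 from 88.6 to 633 FPKM; 2 were lower without SCII 2 or SCII 3 or with quantile normalization and 1 with median centring, and the median was 1.07 without SCII 3. Of 20 unfolded protein response genes 9 were higher (9 over the list alone; median 0.64), with Ppp1r15a from 7.83 ± 0.381 to 40.1 ± 6.34 FPKM and the chaperone Hspa5 from 116 to 292 FPKM. Of these genes, 5 were higher without Sham 1 or Sham 3, 16 were higher and 1 lower without SCII 2, and 8 and 1 without SCII 3. These 4 lists passed camera with the preset correlation; with an estimated correlation the adjusted p was 0.278 for matrix, 0.175 for cell death, 0.087 for antioxidant and 0.188 for unfolded protein genes. Of 14 complement genes 3 were higher (4 over the list alone; median 0.82), with Cd55 from 2.81 ± 0.117 to 18.2 ± 7.62 FPKM. The camera adjusted p was 0.038 (0.0742 with median centring, 0.0682 with quantile normalization, 0.151 with a filter of 5 FPKM, 0.0642 with library weights, 0.069 without SCII 2 and 0.0503 without SCII 3), and adjusted p = 0.236 with an estimated correlation. Complement genes called higher were 1 without Sham 1 or Sham 3, and 4 were lower without SCII 2 and 2 without SCII 3. With median centring 5 were higher and 1 lower, and with quantile normalization 6 were higher. The complement median was 0.30 without a filter and 0.44 with a filter of 5 FPKM. Of 15 cell cycle genes 2 were higher and 1 lower (the same over the list alone; median 0.63), with Cdkn1a, a cell cycle inhibitor, from 12.5 ± 2.93 to 48.0 ± 8.29 FPKM. The camera adjusted p was 0.038, and adjusted p = 0.668 with an estimated correlation. This call was lost without Sham 1 (0.0537), Sham 2 (0.0512) or SCII 2 (0.312), with quantile normalization (0.0514) and with library weights (0.256), and the median relative to all genes was 0.18 without SCII 2. Cell cycle genes called higher were 1 without Sham 1, Sham 2, Sham 3 or SCII 1, and 3 were higher and 2 lower without SCII 2.

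Among lncRNAs, 243 transcripts were higher and 83 lower of 5340 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 239 and 79 of these changed by at least 1 on the log2 scale. The groups did not overlap in 42.5% of transcripts, where chance gives 10%; SCII lay above Sham in 857 of these and below in 1414, the reverse of the balance among called transcripts. The tables used here do not pair the identifiers with gene names. NONRATT019147.2 was close to 0 in the 3 Sham libraries and had 20.7, 66.2 and 12.3 FPKM in SCII 1, 2 and 3 (log2 change 4.75 ± 0.57, adjusted p = 0.0097). NONRATT006315.2 was likewise close to 0 in Sham and had 35.4, 11.7 and 22.8 FPKM in SCII (4.47 ± 0.40, adjusted p = 0.0046). Its Sham values were 1.95e-22 FPKM or lower, too small to be counted reads. Transcripts with identical sequence parts can share reads here too, which was not tested, so a change of a single transcript need not be one of its locus. NONRATT016576.2 had 37.6, 46.4 and 25.6 FPKM in Sham and 0.0355, 0.0011 and 3.48 FPKM in SCII (−4.45 ± 0.61, adjusted p = 0.013). NONRATT003976.2 had 33.7, 41.8 and 68.2 FPKM in Sham and at most 8.92 FPKM in SCII (−4.44 ± 0.89, adjusted p = 0.038). Of these 4, NONRATT006315.2 kept its call without each single library. NONRATT019147.2 lost it without Sham 1 (adjusted p = 0.0519) or Sham 2 (0.0503), and NONRATT016576.2 without Sham 1 (0.0640), Sham 2 (0.0632) or Sham 3 (0.0521). NONRATT003976.2 lost it without Sham 1 (0.110), Sham 2 (0.115), Sham 3 (0.136), SCII 1 (0.109) or SCII 2 (0.0677). The counts of higher and lower transcripts were 24 and 12 without Sham 1, 32 and 15 without Sham 2, 46 and 18 without Sham 3, 94 and 38 without SCII 1, 217 and 143 without SCII 2, and 169 and 84 without SCII 3. The share called was 6.10% of lncRNAs and 15.0% of mRNA genes. Among mRNA genes of matched expression it was 16.6% (15.6% to 17.8% over 100 draws), with genes not being independent replicates. The lncRNAs were tested as single transcripts and the mRNA genes as sums over transcripts, so these shares also differ in feature level. Of mRNA transcripts tested singly, 9.96% were called, without matching on expression.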

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

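All tests of explanations in this part were chosen after the results were seen. A signal also appeared in data outside the gene-level comparison. Of 6102 mRNA transcripts without a matched symbol that passed the filter, 399 were higher and 154 lower in SCII by limma (Benjamini-Hochberg adjusted p under 0.05). Of all 20784 mRNA transcripts tested, which include these and share their fit and adjustment, 1568 were higher and 502 lower (9.96%). The share called was therefore not larger among those without a symbol.

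SCII 2 stood apart from SCII 1 and SCII 3 in neuron genes, by a median log2 gap of −2.58 over the list, and the gap of astrocyte markers (−2.54) and of myelin markers (−2.52) was of similar size. Scaling of the whole library would remove the gap on median centring, but it was still −2.12, with an upper quartile of −1.43. A smaller share of cord tissue in the library would lower microglia with the neurons, but the gap of the homeostatic microglia list was −0.37, with a lower quartile of −0.82, above the upper quartile of the neuron gaps (−1.88); infiltrating macrophages express some of these microglia genes, and the gap of endothelial genes was −0.02. Markers of tissue around the cord were higher in SCII 2, as such a smaller share would give: meningeal and fibroblast markers by a median of 0.50 (quartiles 0.36 and 1.51) and Schwann cell and nerve root markers by 0.78 (0.64 and 0.93). Some members of the endothelial and microglia lists were also lowest in SCII 2. In SCII 1, 2 and 3, Slco1c1 had 4.56, 0.634 and 6.96 FPKM, Slco1a4 2.49, 1.10 and 4.26 FPKM and Slc2a5 0.628, 0.0301 and 1.13 FPKM. These genes were named for their falls and do not stand for their lists. The list medians and these members point different ways, so whether less cord tissue was the whole cause or a part stays open. A more severe loss of neurons and macroglia in this sample also stays open, as the labels give no measure of injury within the group and no biological explanation was tested.

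Of 10 Schwann cell and nerve root markers 5 were higher in SCII (8 over the list alone), with a median of 1.79 relative to all genes; camera gave an adjusted p = 0.327 with an estimated correlation, and 1 marker was higher without Sham 1 or without Sham 3. Scaling was argued against, since after median centring the list median was 1.68 and 5 members still passed. A larger piece of nerve root would keep the ratios of Schwann myelin genes to Mpz, and 2 of 5 ratios separated the groups: Cldn19 by −0.55 and Ncmap by −0.42 on the log2 scale, while Pmp22 stayed between 46.7% and 48.9% of Mpz in all 6 libraries. More nerve root in the SCII libraries may therefore account for part of the rise and cannot be told apart from induction in Schwann cells, because myelin genes of a cell can also rise together. The injury itself stays an open, untested explanation.

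The most abundant globin copies (Hba-a1, Hba-a2 and Hbb) and other red cell genes parted in SCII 2, but not every copy was low there: Hbb-bs had 4459 FPKM in SCII 2, 5827 and 4163 FPKM in SCII 1 and 3 and 880.1 to 1211 FPKM in Sham, and Hba-a3 was highest in SCII 2 (208 FPKM). The globin copies summed to 13691 FPKM there and to 27257 to 79468 FPKM in the other 5 libraries, whereas Alas2, an enzyme of haem synthesis, had 910 FPKM in SCII 2 and 66.1 to 433 FPKM in the others. Blood content alone would keep the ratios of red cell genes to Hba-a1, but for Ahsp, Alas2, Epb42 and Slc4a1 the log2 ratio in SCII 2 exceeded the highest other library by at least 4.42. Reads shared between the near-identical copies summed here, within the alpha or the beta family, would keep the ratio of the family sums. It was 1.68 in SCII 2 and 0.740 to 0.857 elsewhere. The sums hold only copies matched to a symbol, so the ratio cannot tell whether reads were shared with unmatched transcripts. Which process gave these values was not settled, and no biological explanation was tested.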

How the results depend on the processing

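Transcript-level features, library weights, the counts per list without single libraries and the splits of the libraries were chosen after the data were seen; the other alternatives were planned. No named gene and no primary list changed direction by camera under any alternative run. Of 48 named genes 47 passed, and 34 of these passed in every fit without a single library; 3 of 4 named lncRNAs lost the call in at least 1 such fit, and 3 without a filter and 2 with a pseudocount of 0.1. The labels state no pairing by replicate number. Deviations of same-numbered samples from their group means correlated across genes at 0.06, 0.28 and 0.23 for mRNA and at −0.04, 0.05 and 0.04 for lncRNA. Differently numbered samples gave −0.28 to 0.24 for mRNA, and Sham 3 correlated slightly better with SCII 1 (0.24) than with SCII 3. With 3 samples per group and SCII 2 apart, these correlations cannot tell whether the numbers pair the samples. With the replicate block, which has fewer residual degrees of freedom, 823 mRNA genes were higher and 105 lower, 61 lncRNAs were higher and 21 lower, and 4 primary lists were called lower in place of 2, with homeostatic astrocyte (adjusted p 0.0299) and myelin (0.0062) markers added. The block also gave a call to the meningeal list (0.0431), 8 Schwann markers higher in place of 5 and 3 hypoxia genes in place of 7, and it ended the calls of Snca, Idi1, Ndufb5, Rps2 and Fabp4. It likewise ended the call of Vcam1 and left 0 oligodendrocyte precursor and 0 cell cycle genes lower. With median centring 1444 mRNA genes were lower and with quantile normalization 1562, with 4 lists lower in each, the same additions. Without a filter 41 lncRNAs were higher and 30 lower, and 5 lists lower, with motor neuron genes also added; with 5 FPKM in 3 libraries 192 mRNA genes were lower and lncRNA counts were 100 and 16. With a pseudocount of 0.1, 231 mRNA genes were lower and lncRNA counts were 138 and 25. With a fold threshold 784 and 196 mRNA genes were left, by construction. Library weights, which gave SCII 2 the lowest weight (0.0689), raised the mRNA counts to 2212 and 4201 and the lower lncRNAs to 145, and all 1606 genes of the unweighted fit were among those called. Weights were estimated gene by gene because the default estimation did not converge. Leaving out single libraries gave 382 to 1888 mRNA genes higher, 20 to 3312 lower, 24 to 217 lncRNAs higher, 12 to 143 lower, 7 to 8 lists higher and 1 to 4 lower. All 1606 genes were also called without SCII 2. The share of mRNA genes called was 15.0% unmatched and 16.6% matched on expression, and that of single mRNA transcripts was 9.96% unmatched on expression. Except where stated, the cause was not tested. With an estimated correlation 0 primary lists were called higher and 0 lower by camera (4 at an unadjusted p under 0.05, lowest adjusted p 0.087). The 6 libraries allow 10 splits, too few for a share under 0.05. Each other split mixed Sham and SCII libraries in both groups, so the difference between Sham and SCII entered its spread and its contrast. Such splits do not show what would be called without an injury effect. The real split called 1606 mRNA genes and the highest other split 0 by limma (131 at most at an unadjusted p under 0.05); for lncRNAs it was 326 against 3. For primary lists called by camera it was 9 against 11, and 6 of the 10 splits called at least as many, against 1 for genes and 1 for lncRNAs, the real one. The count tests, the count-based scaling and the neighbour analyses that had been planned were not run, as the values are not counts and lncRNA positions were not used here. Depth is unknown, so what it limits could not be assessed.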

Other observations

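Other cell types and processes, all from lists fixed before the data were examined, gave the following counts by limma. Of 17 inhibitory transmission genes and 19 glutamate receptor and transport genes, 0 passed over all genes or over the list alone (11 and 13 lower at an unadjusted p under 0.05), with medians of −1.14 and −1.03 relative to all genes. Both passed camera at the preset correlation, with an adjusted p = 0.668 with an estimated correlation for each. Without SCII 2, 14 and 17 of them were lower, and without SCII 3, 6 and 7, and the medians were −0.59 and −0.55 without SCII 2. With median centring 2 and 6 were lower, and with quantile normalization 2 and 7. Of 22 nuclear-encoded respiratory chain genes 1 was lower over all genes and 17 over the list alone (median −0.46); Ndufb5 went from 109 ± 2.91 to 60.6 ± 16.2 FPKM. Without SCII 2, 20 were lower, without SCII 3, 10, with median centring 11 and with quantile normalization 4, and the median was −0.30 without SCII 2; Ndufb5 lost its call without a filter, with a pseudocount of 0.1, and without Sham 1, Sham 2, Sham 3 or SCII 1 (adjusted p up to 0.162). Of 24 ribosomal protein genes 1 was higher and 0 over the list alone (median 0.78); Rps2 went from 403 ± 13.4 to 832 ± 269 FPKM and lost its call with median centring, without a filter and without Sham 1, Sham 2, Sham 3 or SCII 1 (adjusted p up to 0.158). Without SCII 2, 14 ribosomal genes were higher, and with quantile normalization 11. Both lists passed camera at the preset correlation, with an adjusted p = 0.668 for respiratory chain genes and an adjusted p = 0.565 for ribosomal genes with an estimated correlation. Of 11 oligodendrocyte precursor markers 1 was higher and 1 lower (1 and 2 over the list alone; median −0.73, camera adjusted p = 0.437); Vcan rose from 7.69 ± 0.540 to 24.6 ± 7.30 FPKM and lost its call without Sham 1 (0.0554) or Sham 3 (0.0513). Precursor markers called lower were 6 without SCII 2 and 3 without SCII 3, the median was −0.29 without SCII 2, −1.13 without SCII 1 and −0.31 without a filter, and the one called lower with all libraries lost its call without Sham 1, Sham 2, Sham 3 or SCII 1. That call was also lost with a replicate block, without a filter, with a filter of 5 FPKM and with a pseudocount of 0.1. Of 19 cholesterol synthesis genes 1 passed (1 over the list alone; median 0.08, camera adjusted p = 0.872), Idi1, from 37.1 ± 1.89 to 62.4 ± 5.85 FPKM. It lost its call without Sham 1, Sham 2, Sham 3 or SCII 1 (adjusted p up to 0.0999), and without SCII 2, 3 were higher and 1 lower. The median was 0.22 without SCII 2, −0.05 without SCII 1, −0.01 without Sham 2 and −0.11 without a filter.

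Of 9 pericyte and smooth muscle markers 4 were lower (4 lower and 2 higher over the list alone; median −0.27, camera adjusted p = 0.283); Higd1b fell from 5.04 ± 0.354 to 1.61 ± 0.529 FPKM and lost its call without Sham 1 (0.0598), Sham 2 (0.0537) or Sham 3 (0.0692). Under median centring or quantile normalization 2 were lower and 1 higher, and with a filter of 5 FPKM 1 was lower and the median was −0.01. The pericyte markers called lower were 1 without Sham 1, 0 without Sham 2 or Sham 3 (5 at an unadjusted p under 0.05 by limma with all 6 libraries), and 2 without SCII 1, and 2 were higher without SCII 2. Of 4 measured ependymal and cilium genes 2 were lower (2 over the list alone, median −0.36, camera adjusted p = 0.132). They were Tekt1 and Foxj1, a regulator of motile cilia that fell from 4.59 ± 1.21 to 0.964 ± 0.292 FPKM. The count lower was 1 without Sham 1, without Sham 2 or without Sham 3. Without a filter the list passed camera (0.00711). With the filter and an estimated correlation its camera adjusted p was 0.668. Of 13 meningeal and fibroblast markers 2 were higher and 1 lower (the same over the list alone; median 0.65, camera adjusted p = 0.0998), with Crabp2 from 1.94 ± 0.910 to 7.84 ± 1.62 FPKM, a call lost without Sham 1 (0.0627). Meningeal markers called were 0 without Sham 1 (2 higher and 1 lower at an unadjusted p under 0.05 by limma with all 6 libraries), 2 higher and 0 lower without Sham 2, 1 and 0 without Sham 3 or SCII 1, and 1 and 1 without SCII 3, and the list passed camera without Sham 2 (0.0498), SCII 1 (0.0297) or SCII 3 (0.0275) and with a filter of 5 FPKM (0.0355). Without SCII 2 the median was 0.24 and the camera adjusted p 0.407. With all libraries and an estimated correlation the camera adjusted p of this list was 0.691. Of 9 erythrocyte genes 4 were higher (5 over the list alone; median 2.32, adjusted p = 0.175 with an estimated correlation), with Hbb-bs from 1085 ± 179 to 4816 ± 888 FPKM. All 9 were higher without SCII 2, and 1 without Sham 1, Sham 2, Sham 3 or SCII 1 or without a filter. Of 4 skeletal muscle and fat markers 1 was higher (1 over the list alone; median 0.95, camera adjusted p = 0.153), Fabp4, from 0.916 ± 0.613 to 6.50 ± 3.52 FPKM. It lost its call without Sham 1, Sham 2, Sham 3 or SCII 1 (adjusted p up to 0.146), without a filter and with a pseudocount of 0.1, the median was 0.60 without SCII 2, 2 members were higher and 1 lower without SCII 3, and 1 and 1 without SCII 2. Egr2, a Schwann cell and immediate early transcription factor, rose from 2.45 ± 0.999 to 25.9 ± 12.96 FPKM. Of the T and B lymphocyte markers 1 was measured, Cd4, at 1.70 FPKM in Sham and 0.941 FPKM in SCII, and it did not pass; without a filter 18 markers were tested, 1 was higher and the list passed camera (0.000158). Of 3 measured sex-linked genes 0 passed (0 at an unadjusted p under 0.05; median 0.14, camera adjusted p = 0.656), and the Y-linked Ddx3y had 31.5 to 40.1 FPKM in all 6 libraries.

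The 5 most abundant lncRNA transcripts of a library held 58.4% to 81.2% of its lncRNA FPKM, with the highest share in Sham 3.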
